A study of Homo sapiens with 16 samples.

How the data were processed

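Explanted lung tissue from 4 control donors and 4 donors with the interstitial lung disease of systemic sclerosis (SSc-ILD), scarring of the lung in an autoimmune connective tissue disease, had been profiled by droplet-based single-cell RNA sequencing. The 13 libraries used the 10x Genomics 3' version 2 chemistry, per the labels. They comprised 5 control libraries (3 of mixed lobes and a lower and an upper lobe of the fourth donor) and 8 SSc-ILD libraries (a lower and an upper lobe of each donor). That libraries of both lobes came from the same donor was read from the numbering in the labels. A further 3 libraries combined RNA with surface proteins read through barcoded antibodies (CITE-seq); the control library was analysed, and the 2 SSc-ILD libraries were not analysed here. Per the series' design text the control libraries were re-used from another series, so library batch and disease group cannot be told apart in any comparison of the groups.

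The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, whole numbers without normalization. Per the submitters' processing notes the version 2 libraries went through Cell Ranger 2.0, the CITE-seq libraries through Cell Ranger 3.0.2, and bcl2fastq and Seurat 2.3.4 were also used, with the genome build GRCh38. Per the labels' protocols tissue was digested with collagenase A and DNase I for the version 2 libraries and with Liberase DL and DNase I for CITE-seq. Each version 2 matrix lists 737280 barcodes, which is the full barcode set and not called cells, and 4738169 barcodes over the 13 libraries held at least 1 count. The series text states 56196 cells; the filter behind that number is not given in the sources used here. A minimum of 1000 UMIs left 49443 barcodes, and the threshold chosen here left 31701 before and 30441 after removal of doublets (12049 control and 18392 SSc-ILD cells). Genes on the Y chromosome, XIST and TSIX (103 in all) were not read.

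Total counts per library ran from 23929856 to 48055738 in controls and from 25828546 to 98320519 in SSc-ILD. A barcode was kept as a cell with UMIs of at least 0.1 times the percentile 99 of the top 3000 barcodes of its library and at least 500 UMIs, at least 200 genes, and at most 20% of UMIs from mitochondrial genes. The resulting UMI minimum was 2499 to 3265 in control and 2851 to 6895 in SSc-ILD libraries, and the median UMI count per cell was 6395 to 10787 and 5886 to 21406. Deeper SSc-ILD libraries tended to have a higher minimum, while the deepest control library, with 48055738 counts, had a minimum of 2652. A higher minimum can leave out more small cells such as lymphocytes. Doublets were scored per library with Scrublet as implemented in Scanpy 1.11.5, and the top 0.8% per 1000 cells were left out. Libraries of the same group were compared for duplicates: over 22 pairs the lowest chi-square per degree of freedom was 56.3, so no pair agreed within sampling noise.

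Cells of at least 1000 UMIs were scaled to 10000 counts, reduced to 2000 variable genes and 40 principal components, joined over 15 neighbours and clustered (Leiden, igraph 0.11.9, resolution 2), which gave 46 clusters. No deposited annotation of cells was used, so cell names are rebuilt here and a difference from the study can come from that. A cluster took the name of the class with the highest mean log2 fold over its fixed markers (21 classes) where at least 3 of them were detected, meaning in 10% or more of its cells and at least 2-fold above the mean of the other clusters. A cluster led by markers of another class stayed unnamed, and 17 classes were named. A rule set after the clusters had been seen kept out clusters with markers of 2 classes and a median UMI count over 1.5 times that of their libraries: cluster 25, with secretory and ciliated markers, held 0.340% of control and 1.25% of SSc-ILD cells, and cluster 44, with mural and endothelial markers, held 0% and 0.571%. Pairs of fibroblast with mural and of endothelial with lymphatic endothelial markers were exempt from that rule. Unnamed cells made up 0.660% of control and 1.95% of SSc-ILD cells. Named classes are called by their class name below and mean cells like that class by these markers.

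Counts were summed over all cells of a class and donor, because cells are not replicates. Sums were tested with edgeR 4.0.16, SSc-ILD against control (quasi-likelihood F test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment at 0.05). No covariates were used, as no batch is labelled within a group. Log2 CPM values were computed with a prior count of 2, while the fits and their folds kept edgeR's default. A donor entered with at least 20 cells of the class and at least 3 donors per group were needed. With the planned cells only 1 control donor had enough mural cells and only 1 SSc-ILD donor enough T cells, so these classes were tested on cells of at least 1000 UMIs, mural cells with at least 5 cells per donor, a change made after the cells had been counted. Lower and upper lobes of SSc-ILD donors were compared with the donor as a block. The pairing was checked on the deviations from the lobe means: same-donor correlations ran from 0.308 to 0.800 in fibroblasts and from 0.446 to 0.867 in macrophages, against at most 0.172 and 0.256 with another donor.

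Fixed gene lists (42, markers of other cell types among them) were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members passed the filter, and again with the correlation estimated from these samples. fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, was run beside it. Shares of cell classes per donor, over cells in named classes, were compared with an exact two-sided permutation test over 70 assignments of 8 donors, which cannot give p below 0.0286, and between lobes with exact sign flips, which cannot go below 0.125. The CITE-seq library has no replicate, so its values come without a test; intervals of 95% around sums of counts are exact Poisson intervals and cover counting error only.

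Genes named in the text followed a rule: adjusted p under 0.05, every SSc-ILD donor above or below every control donor, mean log2 CPM of at least 5, then the largest changes (14 higher and 10 lower in fibroblasts and macrophages, 8 and 6 in the other classes; 5 and 5 between lobes with the same sign in every pair), leaving out sex-linked, polymorphic HLA, immunoglobulin, T cell receptor, mitochondrial and ribosomal protein genes. Of each list the 2 to 4 members with the smallest p were considered. The groups, tests, markers, gene lists, named-gene rule, UMI threshold and most alternatives were chosen before the data were examined. Alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, limma voom with quality weights, no low-count filter, a mitochondrial limit of 10%, a minimum of 1000 UMIs, doublets kept, free RNA subtracted, a lower cluster resolution (0.8, 23 clusters), each library as its own sample, lobes taken alone and each donor left out. A different random seed for the clusters and the removal of cells with mesothelial markers were added after the data had been seen. Gene positions come from the GENCODE annotation of GRCh38. Other software was R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

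The edgeR step was tested on simulated data, with counts drawn from means and dispersions estimated from these donors and 200 genes changed by known folds. The changed genes were drawn from those with an average log2 CPM of at least 5. Recovery therefore holds for such genes only and not for all genes tested. The changed genes were picked at random, so recovery was not measured apart for genes that vary more than most between donors. High recovery in a class without calls does not exclude large changes in such variable genes. In fibroblasts (5980 genes) it recovered 8.96% of 2-fold, 79.1% of 4-fold and 97.0% of 8-fold changes, with 8 false among 131 calls. In endothelial cells (9381 genes) it recovered 11.9%, 94.0% and 100% with 7 false of 144, in macrophages (12539 genes) 35.8%, 92.5% and 97.0% with 7 of 157, and in alveolar type 2 cells (9404 genes) 23.9%, 100% and 100% with 12 of 161. In mural cells (5789 genes) it recovered 4.48%, 59.7% and 84.8% with 2 of 101, and in T cells (7346 genes) 47.8%, 97.0% and 100% with 9 of 172. Between lobes it recovered 59.7%, 98.5% and 100% in fibroblasts (6621 genes, 8 false of 180) and 98.5%, 100% and 100% in macrophages (11743 genes, 18 false of 217).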

Results

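Fibroblasts, endothelial cells, mural cells, macrophages, alveolar type 2 cells and T cells of SSc-ILD lungs were compared with those of control lungs, and lower with upper lobes within SSc-ILD. Values for groups are means ± SD over donors, and log2 folds are edgeR estimates ± SE. The SE was derived as the absolute fold divided by the square root of its F statistic, since edgeR gives none for this test. It adds no evidence beyond the test. Adjusted p comes from edgeR for genes and from camera for gene lists unless another test is named. Each comparison of SSc-ILD with control had 4 donors per group except in mural cells, where 3 control donors entered.

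SSc-ILD fibroblasts had more transcripts of POSTN, COMP, TAGLN and 2 collagen genes. POSTN, which encodes periostin, a matrix protein of scar tissue, rose by a log2 fold of 7.56 ± 1.11 (adjusted p = 0.0202), from 5.14 ± 10.3 to 871 ± 586 counts scaled to library size (CPM, n = 4 each). COMP, a cartilage matrix protein, rose by 5.05 ± 0.77 from 6.09 ± 8.94 to 205 ± 114 CPM. The contractile gene TAGLN rose by 2.02 ± 0.36 (adjusted p = 0.0468), from 268 ± 81.9 to 1086 ± 261 CPM. The collagen genes COL15A1 and COL8A1 rose by 3.14 ± 0.49 and 2.72 ± 0.41, and CHN1, a regulator of Rac signalling, rose by 3.95 ± 0.53 (adjusted p = 0.0162). PTN, a heparin-binding growth factor, rose by 3.91 ± 0.62 (adjusted p = 0.0205). Counts over all control fibroblasts were few: 7 each for POSTN, CHN1 and PTN, 10 for COMP and 15 for COL15A1. The size of these folds therefore rests on little in controls. TDO2, a tryptophan-degrading enzyme, rose by 6.00 ± 0.80 (adjusted p = 0.0162). It had 3 counts over all control fibroblasts and 1655 over SSc-ILD fibroblasts, a ratio of 88.7 in CPM terms with a counting interval of 30.3 to 430. That ratio pools the donors, and its interval covers counting error only. GALNT15, a glycosyltransferase, fell by 3.87 on the log2 scale (SE 0.56) and ADAMTS4, a protease that cleaves aggrecan, fell by 2.15 (SE 0.34), both with adjusted p = 0.0202.

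Of 6446 genes tested in 275 control and 704 SSc-ILD fibroblasts, edgeR called 12, 9 higher and 3 lower, and 501 had an unadjusted p under 0.05. The 2 calls outside the naming rule, looked up after their values were seen, were ENTPD1, with 2 counts over control and 372 over SSc-ILD cells, and FAM134B, which fell by 3.43. The ENTPD1 counts are unscaled, from 2011993 UMIs in control and 12517399 in SSc-ILD fibroblasts. Donor values did not overlap in 269 genes (4.17%), where 2.86% would separate by chance. The count rested on few donors: it was 0 without control donor 4 or SSc-ILD donor 3, 1 without control donor 1, 4 without control donor 2, 6 without control donor 3 and 19 without SSc-ILD donor 2. With upper lobes only in SSc-ILD it was 0 of 5175 genes. For POSTN in fibroblast cells, SSc-ILD against control, the log2 fold was 6.77 without control donor 4 (adjusted p = 0.0828). Most cells of both groups lay in cluster 22 (SFRP2, COL1A1, PLA2G2A), while cluster 36 (TCF21, SCN7A) drew 75.2% of its cells from controls.

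**Figure D1:**
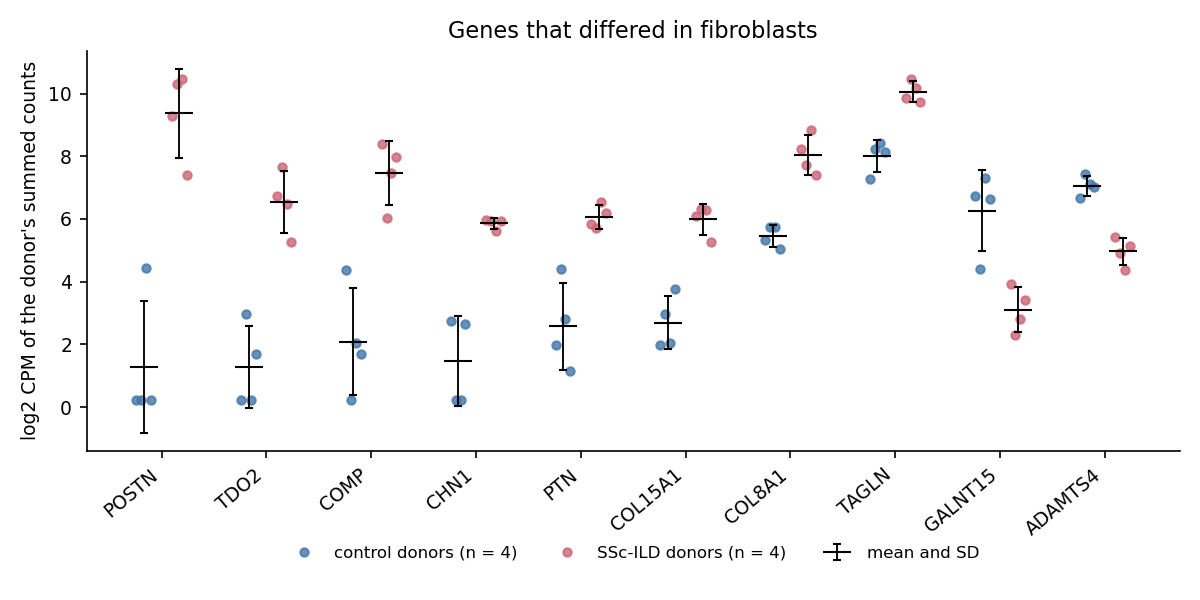
Log2 CPM of the summed fibroblast counts per donor (y axis) for the 10 named genes (x axis), with 1 point per control (n = 4) or SSc-ILD donor (n = 4) and bars for mean and SD. SSc-ILD donors lay above all controls in 8 genes, POSTN foremost with means of 9.37 against 1.29, and below them in GALNT15 and ADAMTS4.

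Myofibroblast and contractile genes were the fibroblast list with the strongest change: all 13 members were higher, with a median log2 fold of 2.02. Of these, 3 rose over all genes tested and 10 rose when adjusted over the list alone, among them ACTA2, the smooth muscle actin of myofibroblasts (2.86 ± 0.54). Of 16 collagen genes 15 were higher with a median of 1.58; 2 rose over all genes and 9 adjusted over the list alone, among them COL6A3 (1.72 ± 0.41) and COL14A1 (2.31 ± 0.62). Of 14 TGF-beta response genes 8 were higher and 6 lower, with a median of 0.28 and adjusted p = 0.404 with an estimated correlation. None was called over all genes; adjusted over the list alone 3 rose, among them TGFBI by 2.24 (SE 0.48), and CILP fell by 2.08 (SE 0.64). The inflammatory genes CXCL8 and CXCL2 fell by 3.29 (SE 0.87) and 2.33 (SE 0.72), adjusted over the list alone, in a list of 14 whose median was -0.68.

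With camera's preset correlation 10 of 17 fibroblast lists passed. Higher lists were myofibroblast and contractile genes (adjusted p = 1.65e-25), collagens (3.94e-15), extracellular matrix crosslinking and turnover (0.0183) and TGF-beta response (0.0205). Lower lists were heat shock genes (1.96e-04, median -0.78), immediate early genes of tissue dissociation (0.0028, median -0.46), adventitial fibroblast genes (0.0088, median -0.73), class II antigen presentation (0.0183, median -1.13), inflammatory genes (0.0195) and the unfolded protein response (0.0274, median -0.25). Only the myofibroblast list held with an estimated correlation (adjusted p = 0.0156). The collagens had adjusted p = 0.189 with an estimated correlation, and the other 8 had adjusted p from 0.404 to 0.654 with an estimated correlation. Without control donor 4 the count of lists was 5 and without SSc-ILD donor 3 it was 6. Matrix glycoproteins (adjusted p = 0.209), interferon-stimulated (0.356), alveolar and lipofibroblast (0.655), hypoxia (0.657), cell cycle (0.761) and senescence genes (0.861) and macrophage markers (0.104) did not pass. Without SSc-ILD donor 2 alveolar and lipofibroblast genes turned from lower to higher and passed (adjusted p = 0.0371). Cell cycle genes tested as lower with a median of 0.03 and a mean of 0.04, and hypoxia genes as lower with a median of 0.12 and a mean of -0.06.

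Endothelial cells of SSc-ILD lungs had more transcripts of COL15A1, COL4A1 and PHLDA3 and fewer of IGFBP3 and ARC. COL15A1 rose by 3.22 ± 0.52 (adjusted p = 0.0175) from 16 ± 7.68 to 157 ± 105 CPM, and COL4A1, a basement membrane collagen, by 2.38 ± 0.39 (adjusted p = 0.0202) from 63.7 ± 33.9 to 352 ± 130 CPM. PHLDA3, a p53-induced brake on AKT, rose by 2.34 ± 0.36 (adjusted p = 0.0162). SLC6A6, a taurine transporter, and MAP1B, a microtubule-binding protein, rose by 3.25 ± 0.62 and 3.17 ± 0.50. ALPL, an alkaline phosphatase, RAI14, an actin-binding protein, and NRGN, a calmodulin-binding protein, rose by 2.80 ± 0.49, 2.17 ± 0.34 and 2.16 ± 0.39. IGFBP3, which binds insulin-like growth factors, fell by 3.17 (SE 0.49) from 686 ± 334 to 76.0 ± 50.2 CPM, and ARC, an activity-induced gene, fell by 3.00 (SE 0.35; adjusted p = 0.0052). The tight junction gene CLDN10 fell by 2.68 (SE 0.49), COL8A1 by 2.67 (SE 0.37), GCHFR, a regulator of tetrahydrobiopterin synthesis, by 2.17 (SE 0.32) and GPX3, an antioxidant enzyme, by 1.75 (SE 0.30).

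Of 9710 genes tested in 553 control and 1606 SSc-ILD endothelial cells, edgeR called 37, 16 higher and 21 lower, with 820 at an unadjusted p under 0.05. With DESeq2 size factors the calls were 14 higher and 21 lower. Donors did not overlap in 492 genes (5.07%, 2.86% by chance). The count was 5 without control donor 4, 8 without control donor 1, 16 without control donor 3 and 23 without SSc-ILD donor 3. The groups drew on different clusters: cluster 39 was 95.4% control, nearly all from control donors 2 and 4 (3 and 4 cells from donors 1 and 3), whereas SSc-ILD cells lay mainly in cluster 12 (ACKR1, POSTN), of which 9.30% were control cells, and cluster 42 (CA4, FCN3), of which 15.4% were. Among cells of at least 1000 UMIs, the named genes differed within cluster 42 by a median of 2.00 in the direction of their call, with 11 of 14 on the same side, and within cluster 28 by 1.14 with 10 of 14, against 2.62 in the class. Outside the rule and chosen after their values were seen, the peptide gene APLN rose by 4.01 and its receptor APLNR went from 3 counts over control to 403 over SSc-ILD cells, and HEY2, an arterial transcription factor, fell by 3.91. The APLNR counts are unscaled, from 3546772 UMIs in control and 15574085 in SSc-ILD endothelial cells.

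**Figure D2:**
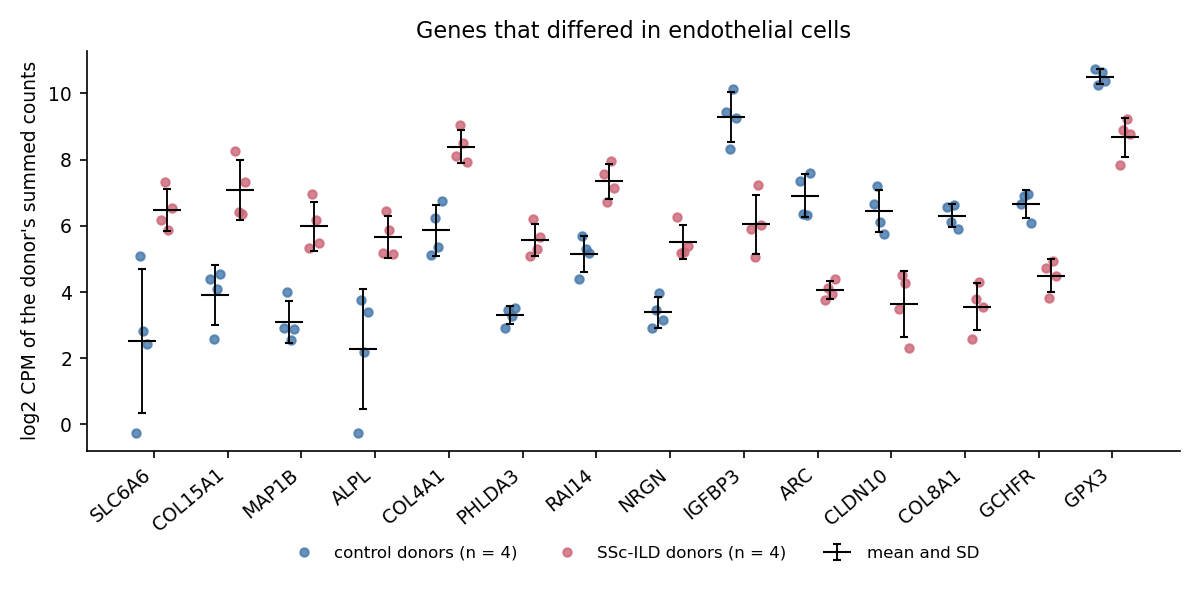
Log2 CPM of the summed endothelial counts per donor (y axis) for the 14 named genes (x axis), with 1 point per control (n = 4) or SSc-ILD donor (n = 4) and bars for mean and SD. The 8 genes on the left were higher in every SSc-ILD donor, such as COL15A1 with means of 7.09 against 3.90, and the 6 on the right lower, such as ARC with 4.05 against 6.91.

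Arterial genes were lower and venous and bronchial genes higher in endothelial cells with camera's preset correlation only (adjusted p = 0.150 and 0.366 with an estimated correlation). Of 12 arterial genes 9 were lower, with a median of -0.92: BMX fell by 1.45 (SE 0.37), DKK2 by 1.99 (SE 0.63) and FBLN5 by 1.19 (SE 0.40), adjusted over the list alone, where 6 fell and 2 rose, CXCL12 among the latter (1.46 ± 0.40), against 0 over all genes. These values do not show fewer arterial cells in SSc-ILD. Cluster 7, whose leading genes include CXCL12, DKK2 and BMX, drew 12.5% of its cells from controls. At 1000 UMIs or more the class held 1112 control and 3073 SSc-ILD cells. Of 15 venous and bronchial genes 12 were higher with a median of 0.51, and COL15A1, VWA1 (1.57 ± 0.45) and SPRY1 (1.42 ± 0.44) rose adjusted over the list alone, 1 of them over all genes. Among p53 targets ZMAT3 (2.91 ± 0.38, adjusted p = 0.0099) and PHLDA3 rose over all genes, and GDF15 (3.77 ± 1.17) rose and BTG2 fell by 0.96 (SE 0.33) adjusted over the list alone. COL4A1 was the 1 mesenchymal-transition gene called over all genes, with COL4A2 (1.91 ± 0.37) and SPARC (1.19 ± 0.37) joining it adjusted over the list alone. Macrophage markers were lower in these cells, with C1QB down by a log2 fold of -2.70 ± 0.65, 0 called over all genes and 4 adjusted over the list alone.

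Camera passed 11 of 15 endothelial lists with its preset correlation. Higher were senescence and p53 targets (adjusted p = 3.39e-04, and 0.150 with an estimated correlation), endothelial-to-mesenchymal genes (0.0011) and venous and bronchial genes (0.0013). Lower were macrophage markers (2.19e-12, median -1.54), immediate early genes (1.31e-05, median -0.56), interferon-stimulated genes (1.73e-05, median -0.53), arterial genes (3.21e-04), heat shock genes (0.0011, median -0.63), inflammatory genes (0.0015, median -1.13), class II antigen presentation (0.0020, median -0.40) and the unfolded protein response (0.0197, median -0.17). None held: adjusted p ran from 0.150 to 0.479 with an estimated correlation. Adjusted over the list alone, 5 immediate early genes fell, led by IER2 at -0.93 ± 0.24, and HERPUD1 of the unfolded protein response fell by 1.43 (SE 0.34). Cell cycle (adjusted p = 0.379), hypoxia (0.841) and alveolar capillary genes (0.966) and alveolar type 2 markers (0.347) did not pass. Hypoxia genes tested as lower with a median of 0.06 and a mean of 0.02. Within the alveolar capillary list CD36 fell by 3.35 (SE 0.72) and GPIHBP1 by 1.69 (SE 0.37), adjusted over the list alone.

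Mural cells, the smooth muscle cells and pericytes of vessels and airways, had 0 of 6236 genes called by edgeR or limma voom, with 528 at an unadjusted p under 0.05 and 26 called by DESeq2. The smallest adjusted p was 0.146, for the pericyte gene RGS5 at 3.39 ± 0.61, which is also a marker used to name these cells. Control cells were few, 81 against 798 over all donors at 1000 UMIs or more, and 9.20% of the single mural cluster. Donors did not overlap in 709 genes (11.4%, 5.71% by chance). Without control donor 3, 1 gene was called.

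All 13 pericyte genes were higher in SSc-ILD mural cells with a median of 0.83 (adjusted p = 1.39e-09, but 0.210 with an estimated correlation), and FAM162B rose by 2.63 ± 0.59 with RGS5 and LAMC3 when adjusted over the list alone, against 0 over all genes. All 11 interferon-stimulated genes were higher (median 1.5, adjusted p = 6.27e-05), 6 of them adjusted over the list alone and 0 over all genes, with IFI27 at 1.73 ± 0.57 and LY6E at 1.86 ± 0.65; MX1 had only 1 control count, so its part in the median rests on little. Collagens were higher (median 0.56, adjusted p = 0.0057). CCL2 and IL6 fell by 3.22 (SE 0.64) and 3.20 (SE 0.88) adjusted over the list alone, in inflammatory genes with a median of -0.84 (adjusted p = 4.55e-04). Smooth muscle contraction genes were lower (median -0.66, adjusted p = 3.61e-04), as were myofibroblast and contractile genes (median -0.73, adjusted p = 0.0032), and ACTG2, the enteric smooth muscle actin, fell by 1.61 (SE 0.44) adjusted over either list alone. Immediate early genes (median -0.65, adjusted p = 1.87e-07) and heat shock genes (median -0.91, adjusted p = 9.28e-07) were lower too. These 8 of 17 lists had adjusted p from 0.210 to 0.699 with an estimated correlation, and without control donor 4 the count was 5.

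Other mural lists did not pass: macrophage markers (adjusted p = 0.0981), TGF-beta response (0.453), unfolded protein response (0.522), hypoxia (0.587), senescence (0.587), matrix glycoproteins (0.587), fibroblast markers (0.587), crosslinking (0.830) and cell cycle genes (0.934). Hypoxia, senescence, matrix glycoprotein and crosslinking genes tested as lower with medians of 0.19, 0.19, 0.32 and 0.25 and positive means. TGF-beta response and unfolded protein response genes tested as lower with medians of 0.02 and 0.04 and negative means. FN1 and PRELP fell by 1.46 (SE 0.40) and 1.49 (SE 0.45) adjusted over the matrix glycoprotein list alone.

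Macrophages of SSc-ILD lungs had higher levels of a fixed set of fibrosis-associated genes, although no single gene passed. In the fibrosis-associated list 23 of 24 members were higher with a median log2 fold of 1.47 (adjusted p = 4.93e-21, and 0.0334 with an estimated correlation). Adjusted over the list alone 11 rose, against 0 over all genes: A2M, a protease inhibitor, by 1.64 ± 0.24, SPP1, which encodes osteopontin, by 4.04 ± 0.82, TREM2, a lipid-sensing receptor, by 1.32 ± 0.28 and the chitinase CHIT1 by 5.52 ± 1.20. Cell cycle genes were higher in 21 of 22 (median 1.21, adjusted p = 1.93e-18, but 0.204 with an estimated correlation), with 11 up adjusted over the list alone and 0 over all genes, CDK1 by 1.67 ± 0.46 and TOP2A by 2.16 ± 0.64. LIPA, a lysosomal lipase, rose by 1.43 ± 0.31 and CD36, a lipid scavenger receptor, by 1.68 ± 0.49, adjusted over the lysosome and lipid list alone, where 3 passed and 0 over all genes. Alveolar macrophage genes were lower in 17 of 20, with CES1 at -1.17 ± 0.31 and GLDN at -1.17 ± 0.45, but 0 were called over all genes or over the list alone, and adjusted p was 0.638 with an estimated correlation.

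Among 12822 genes tested in 6932 control and 9565 SSc-ILD macrophages, edgeR and limma voom called 0, with 1061 at an unadjusted p under 0.05 and 123 called by DESeq2; the smallest adjusted p was 0.210. Donors did not overlap in 566 genes (4.41%, 2.86% by chance). Without control donor 3, 1 gene was called. Clusters differed between the groups: clusters 1, 26 and 38 were 92.1%, 96.7% and 94.1% control, and clusters 4, 17 (CHIT1, SPP1), 24 and 40 were 4.60%, 5.30%, 6.30% and 3.10% control. A single library gave 83.9%, 59.9% and 78.3% of clusters 1, 26 and 38 and 53.7%, 29.8%, 64.8% and 66.5% of clusters 4, 17, 24 and 40. Camera passed 7 of 19 lists, of which the fibrosis-associated list alone held with an estimated correlation. Besides those above, interferon-stimulated genes (median 0.73, all 22 higher) and lysosome and lipid genes (median 0.42) passed with adjusted p = 8.82e-07 each, and so did fibroblast markers (median 1.87, adjusted p = 0.0107), with 3 higher adjusted over the list alone and 0 over all genes. Alveolar macrophage genes (median -0.35, adjusted p = 2.41e-04) and heat shock genes (median -0.25, adjusted p = 0.0257) were lower. These 5 lists had adjusted p from 0.246 to 0.673 with an estimated correlation.

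Macrophage lists that did not pass were inflammatory genes (adjusted p = 0.0588), monocyte genes (0.0870), hypoxia (0.148), T cell markers (0.148), secretory epithelial markers (0.384), unfolded protein response (0.391), senescence (0.536), complement and scavenger receptors (0.536), alveolar type 2 markers (0.639), endothelial markers (0.665), immediate early genes (0.741) and class II antigen presentation (0.843). CD14 rose by 1.03 ± 0.23 adjusted over the monocyte list alone. Class II genes tested as lower with a median of -0.09 and a mean of 0.12.

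Alveolar type 2 cells, the surfactant-making epithelium, gained TIMP3, an inhibitor of matrix metalloproteinases, by 3.30 ± 0.36 (adjusted p = 0.0045), from 13.8 ± 4.80 to 136 ± 54.1 CPM. NDNF, a secreted neurotrophic factor, and FN1, which encodes fibronectin, rose by 1.66 ± 0.28 and 1.58 ± 0.26, and LURAP1L, an activator of NF-kappa B signalling, fell by 2.24 (SE 0.37), each with adjusted p = 0.0482. ABCC3, IGFBP2 and EMB, outside the rule and chosen after their values were seen, were higher by 3.19, 3.31 and 2.61. Of 9619 genes tested in 732 control and 950 SSc-ILD cells, edgeR called 10, 8 higher and 2 lower, with 934 at an unadjusted p under 0.05; donors did not overlap in 540 genes (5.61%, 2.86% by chance). Leaving out control donors 1 to 4 gave 2, 0, 3 and 2 genes and leaving out SSc-ILD donors 1 to 4 gave 1, 4, 1 and 17. The count was 1 with a mitochondrial limit of 10%, 2 with upper lobes only and 44 with lower lobes only in SSc-ILD. For TIMP3 in alveolar type 2 cells, SSc-ILD against control, the log2 fold was 3.23 without control donor 2 (adjusted p = 0.0601). Nearly all cells lay in cluster 5 in both groups.

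In alveolar type 2 cells p53 targets were higher (13 genes, median 0.73, adjusted p = 9.39e-05, but 0.192 with an estimated correlation). ZMAT3 rose by 1.87 ± 0.40, MDM2 by 1.29 ± 0.32 and PHLDA3 by 1.26 ± 0.36 with RRM2B, 4 adjusted over the list alone and 0 over all genes. Transitional and basaloid genes were higher (median 0.36, adjusted p = 0.0270), with the metalloproteinase MMP7 up by 2.49 ± 0.55 and the growth factor MDK by 1.96 ± 0.50, 2 adjusted over the list alone and 0 over all genes. Interferon-stimulated genes were higher (median 0.74, adjusted p = 0.0399), a direction that turned without SSc-ILD donor 2 (adjusted p = 0.638). Lower lists were lipid synthesis (median -0.53, adjusted p = 0.0111), the unfolded protein response (median -0.20, adjusted p = 0.0152; DNAJB9 fell by 1.21, SE 0.25, with 3 adjusted over the list alone and 0 over all genes) and inflammatory genes (median -1.15, adjusted p = 0.0331; CXCL8 fell by 2.10, SE 0.56, the 1 call adjusted over the list alone). These 6 of 14 lists had adjusted p from 0.192 to 0.772 with an estimated correlation, and without control donor 2 the count was 2. Class II antigen presentation (adjusted p = 0.0744), surfactant genes (0.292), immediate early genes (0.292), airway secretory genes (0.514), macrophage markers (0.586), heat shock genes (0.591), hypoxia (0.621) and cell cycle genes (0.976) did not pass.

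T cells of SSc-ILD lungs had lower levels of all 13 cytotoxic effector genes, with a median log2 fold of -0.45 (adjusted p = 1.86e-06); KLRD1, a receptor of killer cells, was at -1.20 ± 0.37, perforin (PRF1) at -0.98 ± 0.33 and NKG7 at -1.01 ± 0.37. Of these 13, 0 were called over all genes and 0 adjusted over the list alone, and the list had adjusted p = 0.311 with an estimated correlation. CD27, a costimulatory receptor of naive and memory cells, rose by 1.43 ± 0.28, the 1 gene that passed adjusted over the list alone among 12 naive and memory genes (median 0.48, adjusted p = 0.0024) and among 15 activation and exhaustion genes (median 0.43, adjusted p = 0.0080), against 0 over all genes. Interferon-stimulated genes were higher in 18 of 20 (median 0.50, adjusted p = 2.89e-05) and the unfolded protein response lower (median -0.31, adjusted p = 7.27e-04). Each of these 5 of 13 lists had adjusted p = 0.311 with an estimated correlation. Of 7680 genes tested in 2715 control and 2242 SSc-ILD cells of 1000 UMIs or more, edgeR and limma voom called 0, with 558 at an unadjusted p under 0.05 and 10 called by DESeq2; the smallest adjusted p was 0.133. Without control donor 2, control donor 3 or SSc-ILD donor 3, 1 gene was called. Donors did not overlap in 298 genes (3.88%, 2.86% by chance).

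T cell lists that did not pass were inflammatory genes (adjusted p = 0.0975), class II antigen presentation (0.0975), heat shock genes (0.224), macrophage markers (0.369), immediate early genes (0.607), cell cycle (0.719), hypoxia (0.720) and senescence genes (0.815). CCL3 fell by 1.25 (SE 0.27) adjusted over the inflammatory list alone. Hypoxia genes tested as lower with a median of 0.04 and a mean of -0.03.

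Endothelial and mural cells made up a larger share of named cells in every SSc-ILD donor than in any control donor. Endothelial cells were 9.16 ± 1.62% of SSc-ILD and 3.83 ± 2.03% of control cells, and mural cells 2.65 ± 1.84% and 0.414 ± 0.512% (SD, n = 4 each). Basal epithelial cells were 2.26 ± 2.03% against 0.0376 ± 0.05%, and plasmacytoid dendritic cells 0.141 ± 0.148% against 0 of 11970 control cells, which allows up to 0.0251%. That limit, 3 divided by the pooled control cells (about 95%), covers counting error only and not variation between donors. These 4 classes had an exact two-sided permutation p of 0.029, the smallest possible, and an adjusted p of 0.121, so no class passed. At this floor, with 17 classes adjusted together, a class could pass only if many more separated at once. The separation did not hold under every setting. Among cells outside the macrophage and monocyte classes endothelial cells were 24.1% against 14.8% (exact p = 0.143) and mural cells 7.43% against 1.44% (exact p = 0.0571). With lower lobes only mural cells were 2.31% against 0.414% (exact p = 0.2) and plasmacytoid dendritic cells had exact p = 0.429, and with upper lobes only basal cells had exact p = 0.114. Plasmacytoid dendritic cells averaged 0.0683% without SSc-ILD donor 4, and mural cells 1.73% without SSc-ILD donor 2 and 0.165% in controls without control donor 2, where control basal cells averaged 0.015%. T cells were 0.756 ± 0.932% against 2.71 ± 0.875% (exact p = 0.0571), 7.52% against 16% at 1000 UMIs or more (exact p = 0.114), and 1.74% against 11.4% outside the macrophage and monocyte classes (exact p = 0.029, donors apart). T cell donors were also apart by centred log ratio and with lower lobes only, and the SSc-ILD mean was 0.293% without SSc-ILD donor 4. Fibroblasts were 4.15 ± 2.71% against 1.97 ± 0.584% (exact p = 0.171) and macrophages 50.2 ± 15.3% against 61.4 ± 11.3% (exact p = 0.314). The other 10 classes had exact p from 0.286 to 1. Among them alveolar type 1 cells were 0.191% against 0.358%, but 0.029% with lower lobes only in SSc-ILD. The UMI minimum reached 6895 in SSc-ILD and 3265 in control libraries, which bears on small cells such as T cells.

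**Figure D3:**
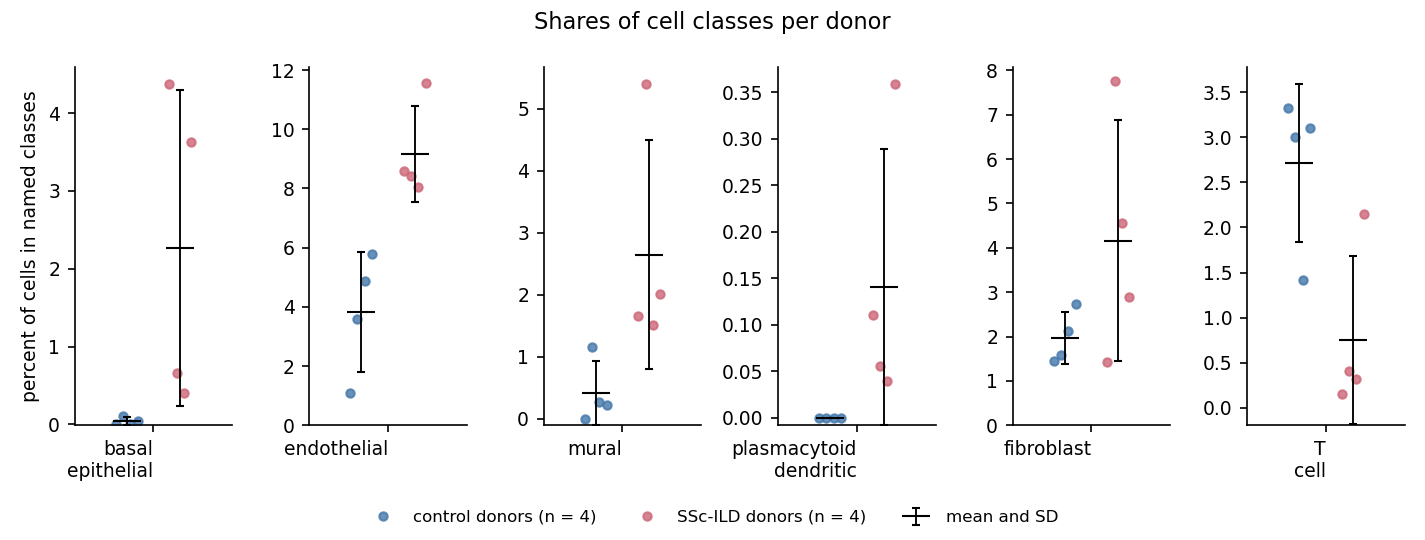
Percent of a donor's named cells (y axis) in cell classes (x axis), with 1 point per control (n = 4) or SSc-ILD donor (n = 4) and bars for mean and SD. Endothelial cells averaged 9.16% in SSc-ILD and 3.83% in control, and mural cells 2.65% and 0.414%, without overlap of donors.

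Fibroblasts of the lower lobes of the 4 SSc-ILD donors had more KRT8, TM4SF1 and AQP1 and less RAMP1 and IGFBP7 than those of the upper lobes. KRT8, an epithelial keratin, was higher by a log2 fold of 5.87 ± 0.90 (adjusted p = 0.0331), TM4SF1, a membrane protein of the tetraspanin-like family, by 4.07 ± 0.38 (adjusted p = 0.0030), and the water channel AQP1 by 3.90 ± 0.35 (adjusted p = 0.0030). The chemokine CXCL1 was higher by 3.58 ± 0.36 and PERP, a desmosomal p53 target, by 2.91 ± 0.36. RAMP1, a receptor-modifying protein, was lower by -1.39 ± 0.19 (adjusted p = 0.0305) and IGFBP7 by -1.01 ± 0.15 (adjusted p = 0.0322). Of 7086 genes tested with the donor as a block, edgeR called 14, 12 higher and 2 lower, with 457 at an unadjusted p under 0.05. Cells with mesothelial markers were 10.2% of lower-lobe and 0.47% of upper-lobe fibroblasts, and the lower-lobe ones came from donors 2 (15 of 132 cells) and 3 (13 of 60), with 0 of 35 and 0 of 48 in donors 1 and 4. Without them the count was 0, RAMP1 included, and the mean paired difference of KRT8 went from 4.48 to 1.62, whereas RAMP1 went from -1.45 to -1.44. The count was 33 without SSc-ILD donor 1, 0 without donor 2, 2 without donor 3 and 73 without donor 4.

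In macrophages lower and upper lobes had 0 of 11905 genes called by edgeR, with 1047 at an unadjusted p under 0.05, 73 called by DESeq2 and 203 by limma voom. Without SSc-ILD donor 2 edgeR called 6 genes and without donor 4 it called 1. Shares of basal, ciliated and secretory epithelial cells were higher in the lower lobe of all 4 donors, with means of 3.57% against 0.951%, 10.5% against 3.52% and 10.3% against 3.90%. B cells (0.110% against 0.344%), T cells (0.405% against 1.11%), dendritic cells (1.79% against 2.80%) and monocytes (6.09% against 7.80%) were lower in all 4, and in each of these 7 classes the exact sign-flip p was 2 in 16, the smallest possible. The means changed with single donors: basal cells were 3.02% against 0.0972%, secretory cells 5.32% against 0.594%, ciliated cells 8.58% against 1.09% and dendritic cells 1.17% against 2.31% without SSc-ILD donor 1, and monocytes 1.70% against 3.79% without donor 2. Without donor 4 ciliated cells were 5.63% against 3.81%, T cells 0.121% against 0.464% and B cells 0.0290% against 0.0717%. At 1000 UMIs or more B, T and dendritic cells each had 1 pair of the other sign, and with a mitochondrial limit of 10% B cells and ciliated cells did. So did ciliated cells with the second seed and at the lower cluster resolution. Alveolar type 1 cells were in no pair higher in the lower lobe (0.0290% against 0.352%, exact p = 0.25; 0.0387% against 0.0835% without donor 4). In 1 pair both lobes had 0 of these cells, a tie. The 8 of 17 classes higher in all pairs or in none became 12 without SSc-ILD donor 2. This count cannot fall when a donor is left out, and fewer pairs more easily lie on the same side. The rise therefore says nothing about how stable the shares are.

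Surface proteins in the CITE-seq control library followed the RNA-defined classes for 10 of 17 antibodies, counted over 8 classes. THY1, a fibroblast surface protein, was highest in fibroblasts at 448 per 1000 antibody counts (counting interval 444 to 453), podoplanin (PDPN) in lymphatic endothelial cells at 513 (509 to 517) and EPCAM in alveolar type 2 cells at 389 (386 to 393). MCAM (223) and THBD (183) were highest in endothelial cells, CD163 (263) and SIGLEC1 (25.8) in macrophages, CD14 (60.6) in monocytes, CD55 (235) in alveolar type 2 cells and CD207 (875) in dendritic cells, the last from 35 cells with a median of 269 antibody counts and a mean centred log ratio of -0.79. Given that median, most of the 68100 CD207 counts came from a minority of these cells, so 875 is not a typical level. By centred log ratio CD207 was still highest in dendritic cells. CD34 protein was highest in fibroblasts (364) and its RNA in endothelial cells, and FCGR3A protein in macrophages (202) and its RNA in monocytes. DPP4 protein was highest in lymphatic endothelial cells (359) and its RNA in alveolar type 2 cells. CDH11, PDGFRB and CD1C protein were highest in NK cells, a class of 20 cells with a median of 114.5 antibody counts, and PDGFRA in monocytes at 5.53. The CD207 counts fill most of the dendritic total, which lowers CD1C per 1000 counts there (52.9), so this ranking of CD1C rests on the scaling. By centred log ratio CD1C was highest in dendritic cells, the class of its RNA (2.36 against 1.98 in NK cells), but CD163 was highest in monocytes (1.92 against 1.87 in macrophages), away from its RNA. This single library gave 2878 cells with a median of 20434 UMIs from 113986177 RNA counts and 11058676 antibody counts, above a minimum of 9504 UMIs, and its values come without a test.

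Coordinates of the named genes are given on GRCh38 with the identifiers of the deposited files. POSTN (ENSG00000133110) lies on chromosome 13 from 37562583 to 37598844, TDO2 (ENSG00000151790) on chromosome 4 from 155854738 to 155920406, COMP (ENSG00000105664) on chromosome 19 from 18782773 to 18791305 and CHN1 (ENSG00000128656) on chromosome 2 from 174798809 to 175005381. PTN (ENSG00000105894) lies on chromosome 7 from 137227341 to 137343774, COL15A1 (ENSG00000204291) on chromosome 9 from 98943179 to 99070792, COL8A1 (ENSG00000144810) on chromosome 3 from 99638475 to 99799226 and TAGLN (ENSG00000149591) on chromosome 11 from 117199370 to 117207464. GALNT15 (ENSG00000131386) lies on chromosome 3 from 16174680 to 16231992 and ADAMTS4 (ENSG00000158859) on chromosome 1 from 161184302 to 161199054. Of the endothelial genes SLC6A6 (ENSG00000131389) lies on chromosome 3 from 14402576 to 14489349, MAP1B (ENSG00000131711) on chromosome 5 from 72107234 to 72209565, ALPL (ENSG00000162551) on chromosome 1 from 21509397 to 21578410 and COL4A1 (ENSG00000187498) on chromosome 13 from 110148963 to 110307157. PHLDA3 (ENSG00000174307) lies on chromosome 1 from 201464278 to 201469237, RAI14 (ENSG00000039560) on chromosome 5 from 34656328 to 34832612 and NRGN (ENSG00000154146) on chromosome 11 from 124739942 to 124747210. IGFBP3 (ENSG00000146674) lies on chromosome 7 from 45912245 to 45921874, ARC (ENSG00000198576) on chromosome 8 from 142611049 to 142614479, CLDN10 (ENSG00000134873) on chromosome 13 from 95433604 to 95579759, GCHFR (ENSG00000137880) on chromosome 15 from 40764068 to 40767708 and GPX3 (ENSG00000211445) on chromosome 5 from 151020591 to 151028988. Of the alveolar type 2 genes TIMP3 (ENSG00000100234) lies on chromosome 22 from 32801705 to 32863041, NDNF (ENSG00000173376) on chromosome 4 from 121035613 to 121073021, FN1 (ENSG00000115414) on chromosome 2 from 215360440 to 215436073 and LURAP1L (ENSG00000153714) on chromosome 9 from 12775020 to 12823060. Of the lobe genes KRT8 (ENSG00000170421) lies on chromosome 12 from 52897187 to 52949954, TM4SF1 (ENSG00000169908) on chromosome 3 from 149369022 to 149377692, AQP1 (ENSG00000240583) on chromosome 7 from 30911853 to 30925517 and CXCL1 (ENSG00000163739) on chromosome 4 from 73869393 to 73871308. PERP (ENSG00000112378) lies on chromosome 6 from 138088505 to 138107419, RAMP1 (ENSG00000132329) on chromosome 2 from 237858893 to 237912106 and IGFBP7 (ENSG00000163453) on chromosome 4 from 57030773 to 57110385.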

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

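The comparison of COL8A1 and COL15A1 between classes was chosen only after both genes had been called in 2 classes. In 11 of 92 groups of 4 donors, 1 donor lay far from the others, measured as its gap to the nearest donor over the whole range of the group. Chance flags about 1 in 20 groups, and no explanation of these gaps was tested.

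COL8A1 moved in opposite directions in 2 cell classes. It rose by a log2 fold of 2.72 ± 0.41 in SSc-ILD fibroblasts and fell by 2.67 (SE 0.37) in SSc-ILD endothelial cells. The difference between the 2 effects over 8 donors was 5.33. Since the donors separate by group in both classes, a permutation test of it can only give its smallest p and adds nothing. COL15A1, the other gene called in both classes, rose in both and differed by 0.116 (exact permutation p = 0.886). No technical or biological explanation of the COL8A1 difference was tested, and library batch and group cannot be told apart.

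POSTN in control fibroblasts had 1 donor above the other 3, which had no count, so the gap was 1 of the range. CHN1 in SSc-ILD fibroblasts had 1 donor below the others, a gap of 0.958 of a narrow range.

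Among cell shares in SSc-ILD, donor 4 lay highest for B cells (gap 0.912), NK cells (0.831), T cells (0.873), mast cells (0.851) and endothelial cells (0.844). Donor 2 lay highest for monocytes (0.865) and mural cells (0.869). Among controls 1 donor had the lowest share of T cells (0.833) and 1 the highest share of secretory epithelial cells (0.842).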

How the results depend on the processing

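Of the alternatives, the second random seed, the removal of cells with mesothelial markers, the changed selection of mural and T cells, and leaving out donors for the lobe shares were tests chosen only after the data were seen. Where a value changed, the cause was not tested unless it is named.

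Among counts of genes, DESeq2 gave more calls than edgeR in every comparison: 53 against 12 in fibroblasts, 26 against 0 in mural cells, 123 against 0 in macrophages, 131 against 37 in endothelial cells, 66 against 10 in alveolar type 2 cells and 10 against 0 in T cells. Between lobes it called 27 against 14 in fibroblasts and 73 against 0 in macrophages. Limma voom gave 6 in alveolar type 2 cells and 203 between macrophage lobes, and stayed within 1.5 times elsewhere, as did DESeq2 size factors throughout.

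Without a filter on low counts edgeR called 296 genes in fibroblasts, 126 in mural cells, 9 in macrophages, 216 in endothelial cells, 144 in alveolar type 2 cells and 116 in T cells, and 331 and 339 between lobes in fibroblasts and macrophages. With each library as its own sample it called 49, 4, 41, 114, 154 and 15 in fibroblasts, mural cells, macrophages, endothelial, alveolar type 2 and T cells; lobes of 1 donor then count as independent, which overstates the number of samples. With lower lobes only for SSc-ILD it called 1 gene in mural cells, 20 in endothelial cells, 44 in alveolar type 2 cells and 1 in T cells. With upper lobes only it called 0 in fibroblasts, 1 in mural cells and 2 in alveolar type 2 cells.

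At the lower cluster resolution mural cells had 2 genes, macrophages 7 and macrophage lobes 4. With doublets kept endothelial cells had 23 genes and alveolar type 2 cells 5, and a mitochondrial limit of 10% left 1 gene in alveolar type 2 cells. At 1000 UMIs or more the fibroblast lobes had 25 genes. Without cells with mesothelial markers they had 0. Subtraction of free RNA and the second seed moved no count of genes by more than 1.5 times.

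The donor block mattered for the lobes of fibroblasts: without the replicate block edgeR called 0 genes against 14 with it, and in macrophages 0 with and without it.

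Leaving out 1 donor at a time gave 0 to 19 genes in fibroblasts, 0 to 1 in mural cells, 0 to 1 in macrophages, 5 to 36 in endothelial cells, 0 to 17 in alveolar type 2 cells and 0 to 1 in T cells, and 0 to 73 and 0 to 6 between lobes in fibroblasts and macrophages. Lists ranged from 5 to 12 in fibroblasts, 5 to 8 in mural cells, 6 to 9 in macrophages, 10 to 12 in endothelial cells, 2 to 6 in alveolar type 2 cells and 4 to 7 in T cells. Fewer donors lower the power of every test.

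With an estimated correlation camera passed 1 list in fibroblasts, 0 in mural cells, 1 in macrophages, 0 in endothelial cells, 0 in alveolar type 2 cells and 0 in T cells, since correlated members carry less evidence than independent ones. Mural lists were 5 with limma voom and 5 with lower lobes only, and T cell lists were 3 with upper lobes only. Over single lists, leaving out a donor left 630 values on the same side of the threshold, ended 67 calls and added 39. Other settings gave 1037, 42 and 23. A list that passed neither as planned nor in the alternative was counted as on the same side whatever its direction. Reversed were 2 lists, both without SSc-ILD donor 2: alveolar and lipofibroblast genes in fibroblasts, then higher with adjusted p = 0.0371 (0.0371 to 0.850 over the donors left out), and interferon-stimulated genes in alveolar type 2 cells, then lower with adjusted p = 0.638 (4.63e-04 to 0.638).

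Of calls of named genes, leaving out a donor kept 116 and ended 133, and other settings kept 393 and ended 61; none reversed. No cell class share passed between SSc-ILD and control under any setting run (0 throughout). Classes higher in the lower lobe in all pairs or in none, with ties as not higher, were 8 as planned, 5 at 1000 UMIs or more, 5 at the lower cluster resolution and 8 to 12 without 1 donor. Leaving out a donor cannot lower this count. Antibodies highest in the class of their RNA numbered 8 to 10 under the settings run.

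With the planned threshold 42 control mural and 120 SSc-ILD T cells were left. On simulated data 4.48% of 2-fold changes were recovered in mural cells, 8.96% in fibroblasts and 47.8% in T cells. All changed genes had an average log2 CPM of at least 5.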

Other observations

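The tests of GCHFR and of free RNA and all tests on other splits of the donors were chosen only after the results had been seen.

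Genes higher in SSc-ILD fibroblasts were weighed against a shift in the mix of fibroblast clusters and against free RNA. Among cells of at least 1000 UMIs, the named higher genes differed within cluster 22 by a median log2 of 4.09, against 4.13 in the whole class. This argues against a shift between these clusters alone as the cause. Cluster 22 had 3 control donors and 923 of the 996 SSc-ILD cells, and a shift in the mix of cells within it was not tested. Free RNA accounted for a median of 0.287% and at most 1.04% of their SSc-ILD counts, which argues against it. A difference between library batches stays open, since the control libraries were re-used from another series and batch and group cannot be told apart. A response to the disease is the candidate explanation that the design names, and it was not tested apart from batch.

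Genes that differ in SSc-ILD endothelial cells were weighed against a shift in the mix of clusters and against less macrophage RNA. Within single clusters the median difference was as low as 1.14, with 10 of 14 genes on the side of their call, against 2.62 in the class; with 3 control donors per cluster, a shift in the mix and a change within cells cannot be told apart. The named lower genes were less abundant in control macrophages than in control endothelial cells by a median log2 of -7.01, which argues against lost macrophage RNA for the lower genes as a set. GCHFR was the exception, 3.17 higher in control macrophages, so its lower level in SSc-ILD endothelial cells may reflect less macrophage RNA, as C1QB was lower there too. Library batch stays open here as well.

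Genes higher in lower-lobe SSc-ILD fibroblasts may come in part from mesothelial cells within the fibroblast class. Without cells with mesothelial markers, which were 10.2% of lower-lobe and 0.47% of upper-lobe fibroblasts, the median paired difference of the 5 named higher genes went from 3.09 to 1.27 and the count of called genes from 14 to 0. RAMP1 and IGFBP7 had paired differences of -1.44 and -0.90 against -1.45 and -1.04 but lost their calls too. The marked lower-lobe cells came from donors 2 and 3 alone (15 and 13), so they leave open the rise in donors 1 and 4, where the named genes were higher as well. The remaining difference, a median of 1.27, may hold further mesothelial cells below the marker limit or a change in fibroblasts, and neither was tested.

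Other splits of the same donors showed how often a regrouping gives as many calls. With 35 splits the smallest possible share is 1 in 35, and these tests were not adjusted for their number. They therefore cannot exclude chance. For genes the real split was the 1 of 35 with as many calls in 3 classes. These were fibroblasts (12 against at most 5 in any other split), endothelial cells (37 against at most 1) and alveolar type 2 cells (10 against at most 5). In mural cells (0 against at most 2), macrophages (0 against at most 1) and T cells (0 against at most 1) no gene was called, so each of the 35 splits had as many by construction and chance was not tested. For gene lists this held in endothelial cells only (11 against at most 9, 1 split of 35). More than 1 split had as many lists in fibroblasts (10 against at most 12, 6 splits), mural cells (8 against at most 10, 15 splits) and macrophages (7 against at most 15, 26 splits). The same was seen in alveolar type 2 cells (6 against at most 10, 20 splits) and T cells (5 against at most 10, 16 splits). Between lobes the 8 possible splits are too few for a share under 0.05: fibroblasts had 14 genes against at most 2 in another split (1 split with as many), and macrophages 0 against at most 1, where all 8 splits had as many by construction.

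Hemoglobin RNA, chosen after its values were seen, did not pass in edgeR: log2 folds of HBB in SSc-ILD were 3.85 ± 0.83 in fibroblasts (adjusted p = 0.127), 2.71 ± 1.00 in macrophages (0.501) and 4.62 ± 1.40 in T cells (0.578), and of HBA2 3.67 ± 0.78 in macrophages (0.307).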
